A study of Escherichia coli with 4 samples.

How the data were processed

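RNA was sequenced from plasmid-free Escherichia coli K-12 MG1655 grown in M9 minimal medium at 37 C and 225 rpm in 250 mL flasks holding 40 mL of culture. The carbon source was 0.2% glycerol or 0.2% glucose, and 2.5 mL of culture was sampled at an OD600 of 2. There were 2 replicates of each carbon source, 4 libraries in all. Per the labels, cells were stabilised with RNAprotect, RNA was extracted with an RNeasy kit and DNA was digested. The series also describes hosts that carry plasmids, which were not analysed here.

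Per the file headers, the authors counted fragments in coding sequences with featureCounts 2.0.1, with reverse strandedness, both ends mapped, no chimeric pairs, a fraction of at least 0.5 of the fragment inside the coding sequence, and no option set to count multi-mapping or multi-overlapping fragments. The deposited counts are whole numbers with no normalisation. The submitters' notes name build ASM584v2. The aligner and any trimming are not given in the sources used here. The deposited log2 table holds log2(TPM + 1), computed by the authors from the same counts and coding lengths. All 17420 of its 17420 values were within 1e-12 of values recomputed from the counts, so the table holds the same data in another unit. No other column held a value per sample (0 columns).

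Total counts were 15809570 and 10211415 for glucose replicates 1 and 2, and 10274845 and 15172230 for glycerol replicates 1 and 2. The chi-square per degree of freedom between replicates, for genes with at least 20 counts in both together, was 50.2 in glucose and 5.42 in glycerol, so that replicates differed by more than counting error. Spearman correlations of counts across genes were 0.9947 between the glucose replicates, 0.9984 between the glycerol replicates and between 0.9623 and 0.9638 across groups. Symbols were taken from a RefSeq table that pairs locus tags with symbols. It held all but 4 of the files' locus tags, 4351 in number, of which 4331 had the same start and end there and 113 were pseudogenes there. Lengths were coding lengths, 99.3% of them multiples of 3, and 20 coding sequences had more than 1 part.

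Python 3.11.15 read the tables and drew the plots with matplotlib 3.10.9, and R 4.3.3 ran the tests. The comparison was glycerol minus glucose, with glucose as the reference. Genes passed edgeR's filterByExpr with a minimum count of 10, which kept 4029 genes with 99.991% of the counts and left out 326. Libraries were scaled by TMM factors (1.058 and 0.9295 for glucose replicates 1 and 2, 1.009 and 1.008 for glycerol replicates 1 and 2). Each gene was tested with edgeR 4.0.16, by the quasi-likelihood F test with robust dispersions, two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The common dispersion was 0.0115. Standard errors of log2 fold changes were the size of the change divided by the square root of F. Levels are in CPM, the count of a gene over the TMM-scaled library total in units of 1e6. Shares of counts were not tested, since an exact permutation test of 2 libraries against 2 cannot give a two-sided p under 0.333.

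The comparison, the tests, 34 gene lists and the rule for named genes were fixed before the data were examined. The rule named the 5 genes with the largest and the 5 with the smallest log2 fold change among those past the threshold with a mean of at least 10 CPM in a group, up to 3 members of each list past the threshold by size of change, or the 2 most abundant members of a list with none, and always glpF, glpK, glpD, ptsG, crp, cyaA, aceA, fliC and rpoS. Neighbours of the genes with the largest and smallest changes could be named with them. Genes outside this rule, namely flhD, flhC, ompF, gltB, gltD, gadA, gadB, ptsH, ptsI, mdh, lexA, recA, members named because 5 or fewer of a list rose, fell or did not pass, and the genes of the lists in the closing section, were chosen after their values were seen. The lists covered glycerol and glucose uptake, central carbon metabolism, other carbon sources, cAMP-CRP signalling, flagella, stress, acid, iron, nitrogen, phosphate, heat shock and SOS responses, ribosomal proteins and translation factors, respiration, ATP synthase and fermentation, the synthesis of amino acids and nucleotides, curli, prophages, porins, chromosome replication, and plasmid markers. Some genes stand on more than 1 list, such as glpX, lamB, the ugp genes, carA, carB and crr. Lists with at least 3 tested members, 33 of them, were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, then with the correlation estimated for each list, with adjustment over the lists. The rotation test fry, which asks whether a list's genes move one way without reference to other genes, was also run.

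For the chromosome, Spearman's rho of log2 fold change and distance from the replication origin was compared with all circular shifts of the gene order. The labels give a batch number equal to the replicate number and do not say what it stands for. Replicates were not paired in the test, a choice fixed before the data were examined, and the paired fit is among the alternatives. The deviations of replicate 1 from its group mean had a correlation of -0.024 between glucose and glycerol over 4029 genes.

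The steps were tested on simulated data with the files' means, dispersions and library sizes. The counts of each gene were drawn independently, with the same dispersion in both groups. In the real libraries the glucose pair spread more widely and members of whole lists moved together. The rates of false calls and of unchanged lists called may therefore differ in the real data. Of genes changed 1.5-fold, 39 of 67 were called in the right direction, of genes changed 2-fold 60 of 67, and of genes changed 4-fold 66 of 66. Of 182 calls 17 (9.34%) were false, more than the nominal rate, and 1 gene was called when nothing had changed. A list of raised genes was called and 0 of 30 unchanged lists were. The axis step gave a p under 0.05 in 5% of 200 draws with no gradient, and in 6% where neighbouring genes were correlated. By circular shifts, the simulated counts with nothing changed gave a p of 0.0303. Simulated counts with a slope of 0.2 log2 units per Mb gave a p of 0.0168, with a recovered slope of 0.204. Each of these was a single draw, so they do not show a fault of the axis step. A p of such a size from a single table does not by itself tell a gradient from none.

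Alternatives were DESeq2 size factors, upper-quartile factors, total counts, factors without the 20 most abundant genes, no filter, a minimum of 50 counts in 2 samples, the DESeq2 1.42.0 Wald test, limma-voom, non-robust dispersions, limma on the deposited log2 values, the replicate number as a block, each library left out, an adjusted p of 0.01, a test against a 1.5-fold change, and other denominators of shares. After the data were examined, limma-voom with a weight per group and a fit without the RpoS and acid resistance lists were added. No GC content was computed, since no genome sequence was used here. The headers set no option to count fragments that match more than 1 copy of a gene. For the insH copies the counts argue that such fragments were counted and spread over the copies. In glucose replicate 1, 7 of the 9 insH copies held 3295 to 3751 counts each. No such even spread was seen for tufA and tufB, which held 317566 and 33629 counts in that library. How shared fragments of other near-identical genes were handled could not be settled. Levels of near-identical genes such as tufA and tufB, gadA and gadB, and the insH copies are therefore uncertain.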

Results

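RNA was sequenced from Escherichia coli K-12 MG1655 that carried no plasmid, grown in M9 minimal medium with 0.2% glycerol or 0.2% glucose as the carbon source. There were 4 libraries in 2 groups, with 2 replicates in each group, and all were sampled at an OD600 of 2. Total counts in coding sequences were 15809570 for glucose replicate 1, 10211415 for glucose replicate 2, 10274845 for glycerol replicate 1 and 15172230 for glycerol replicate 2. The number of coding sequences with 0 counts ran from 77 in glycerol replicate 2 to 131 in glucose replicate 2. The 10 most abundant genes took 12.8% of the counts in glucose replicate 1 and 14.5% in glycerol replicate 1, the lowest and the highest share. The most abundant gene was metE, for the last step of methionine synthesis, in both glucose libraries and ompF, for an outer membrane porin, in both glycerol libraries. Hosts with plasmids, which the series is about, were not analysed here, and the comparison asks how transcripts of the plasmid-free host differed between the carbon sources.

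The 2 glucose libraries differed from each other more than the 2 glycerol libraries did. Over genes with at least 1000 counts in the sum of both replicates, the SD of the log2 ratio of replicates was 0.302 in glucose (2094 genes) and 0.0973 in glycerol (2153 genes). All 30 tested members of the RpoS general stress list and all 18 of the acid resistance list were higher in glucose replicate 1 than in glucose replicate 2, and all 33 iron uptake genes and 50 of 54 ribosomal protein genes were lower. A fit without 1 glycerol library takes its spread from the glucose pair alone, and a fit without 1 glucose library from the glycerol pair, and the counts of genes without each library are given below where they moved by over 1.5 times and by at least 2 genes. The p-values measure the spread between these samples, which may be technical, because the labels do not say that replicates came from separate cultures.

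In glycerol many genes for glycerol uptake and breakdown, for acetate use and the glyoxylate shunt, for the use of other carbon sources and for flagella rose, and many genes for ribosomal proteins and for the synthesis of several amino acids and of nucleotides fell, as did the glucose permease gene ptsG. Of 33 gene lists, 5 were higher and 8 lower by camera with a preset correlation, which treats the genes of a list as nearly independent. None of these kept its call with an estimated correlation (adjusted p = 0.344 to 0.833). With 2 replicates per group that setting left little room for a call. Even the glycerol list, with a median log2 fold change of 4.26, reached an unadjusted camera p of only 0.0104 there. A call lost in that setting therefore does not decide for or against a list. By the rotation test fry the 5 higher lists passed and the 8 lower lists did not (adjusted p of 0.127 to 0.244). Of 4029 genes tested, 1555 (38.6%) passed an adjusted p of 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 834 of them higher in glycerol and 721 lower. The larger changes were mostly increases. By more than 2-fold, 451 genes were higher and 101 lower, and by more than 8-fold, 51 were higher and 1, mqo, was lower. Without glycerol replicate 1 or 2 the test called 763 and 780 genes, of which 193 and 210 were lower in glycerol. Without glucose replicate 1 or 2 it called 2432 and 2189, of which 1224 and 1094 were lower, and 154 genes were lower by more than 2-fold without glucose replicate 1.

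**Figure D1:**
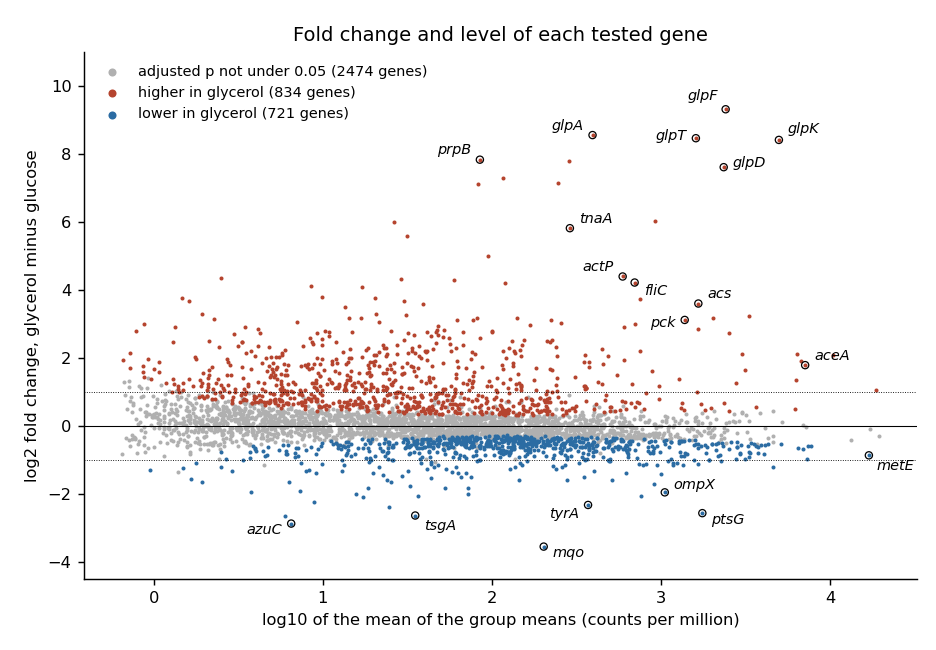
Each point is 1 of 4029 tested genes, with the log10 of its mean CPM (counts per 1e6 of the TMM-scaled library total) on the horizontal axis and its log2 fold change, glycerol minus glucose, on the vertical axis. Red points are the 834 genes higher in glycerol, blue points the 721 lower and grey points the 2474 that did not pass. Dotted lines mark changes of 2-fold, and of the labelled genes glpF, glpA, glpT and glpK stand highest.

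The largest increases were in the genes that take up glycerol and carry it into glycolysis. The gene glpF (b3927), for the glycerol channel of the inner membrane, lies at 4117245 to 4118090 on the minus strand of the chromosome (build ASM584v2). Its level was 7.41 ± 1.53 CPM in glucose (SD, n = 2) and 4808 ± 90 in glycerol. The log2 fold change was 9.31 ± 0.23 (SE), a 637-fold difference with an adjusted p of 1.29e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The neighbouring glpK (b3926), for glycerol kinase, went from 28.9 ± 6.1 to 9912 ± 314 CPM (SD, n = 2), a log2 fold change of 8.41 ± 0.24. The gene for the aerobic glycerol 3-phosphate dehydrogenase, glpD (b3426), rose 195-fold, with a log2 fold change of 7.61 ± 0.25. The gene glpA (b2241), for a subunit of the anaerobic dehydrogenase, rose 376-fold, and glpT (b2240), for the glycerol 3-phosphate transporter, rose 353-fold. Their neighbours glpB, glpC and glpQ had log2 fold changes of 7.80 ± 0.18, 7.14 ± 0.16 and 6.02 ± 0.16.

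Of the 16 tested members of the glycerol list, 11 rose, 0 fell and 5 did not pass over all genes tested. Adjusted over the list alone, 11 rose and 1 fell. The members that did not pass were dhaM, gldA, glpE, glpG and the repressor gene glpR, whose log2 fold change was -0.004. In the log2 TPM table glpE passed by limma (0.29, adjusted p of 0.0396), against 0.24 from the counts. Without glucose replicate 2 it stood at 0.31. The log2 fold change of gldA was 0.27, and 0.45 without glucose replicate 1. The gene glpG had a log2 fold change of -0.37, and it passed with the replicate number as a block (-0.36, adjusted p of 0.0221), with upper-quartile factors (-0.37, 0.0399), with total counts (-0.34, 0.0441) and without glucose replicate 1 (-0.53) or 2 (-0.19). The list took 0.0896 ± 0.0046% of all counts in glucose and 2.77 ± 0.03% in glycerol (SD, n = 2). By camera with a preset correlation between genes of 0.01, and adjusted over 33 lists, the list was higher in glycerol with an adjusted p of 5.22e-44, and the adjusted p = 0.344 with an estimated correlation. The plot of levels of named genes shows the separate libraries.

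**Figure D2:**
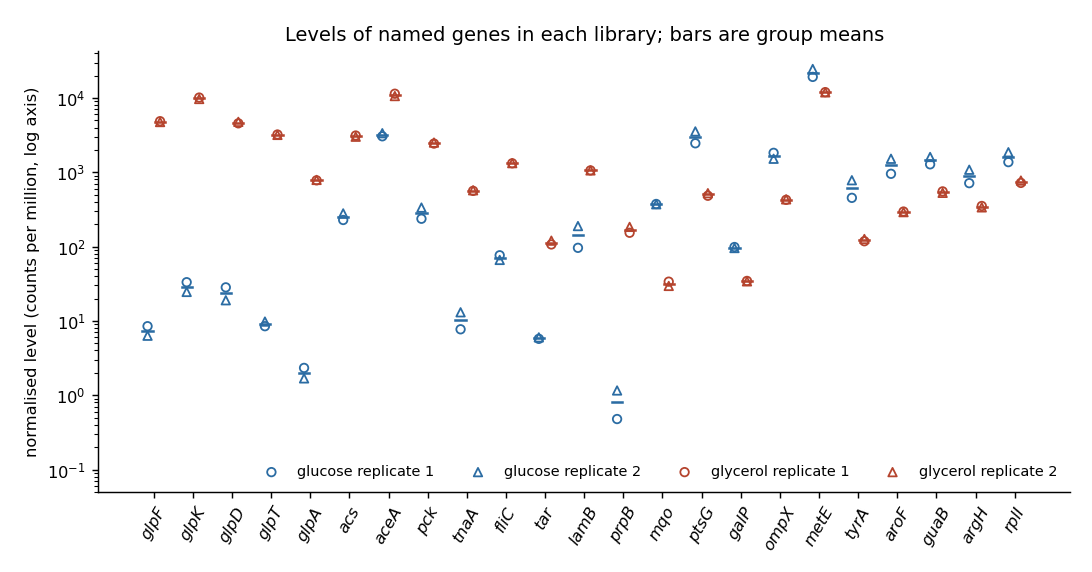
Level in TMM-normalised CPM, on a log axis, of 23 named genes in glucose and glycerol, with circles for replicate 1, triangles for replicate 2 and bars for the mean of each group (n = 2). The 5 glp genes sit above 700 CPM in glycerol and under 40 in glucose.

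Genes for acetate use and the glyoxylate shunt, by which cells make larger carbon compounds from acetyl units, also rose. Of 13 tested members, 10 rose, 0 fell and 3 (ackA, poxB and pta) did not pass, with the same counts adjusted over the list alone. With the replicate number as a block poxB passed (log2 fold change 0.53, adjusted p of 0.00163, against 0.49 and 0.135), and ackA passed with total counts, with factors from all but the 20 most abundant genes and in the log2 TPM table (0.0319, 0.0406 and 0.0326). Both passed without glucose replicate 1 or 2. The gene for acetyl-CoA synthetase, acs (b4069), went from 254 ± 37 to 3067 ± 81 CPM (SD, n = 2), a log2 fold change of 3.60 ± 0.17. Its neighbours yjcH and actP, the latter for the acetate transporter, had log2 fold changes of 4.19 ± 0.15 and 4.39 ± 0.18. The isocitrate lyase gene aceA (b4015) rose 3.44-fold, from 3204 ± 217 to 11010 ± 564 CPM (SD, n = 2). The median log2 fold change of the list was 1.87, with a camera adjusted p of 4.44e-18, and the adjusted p = 0.417 with an estimated correlation.

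Of 7 gluconeogenesis genes, 4 rose, 1 fell and 2 did not pass, with the same counts adjusted over the list alone. The gene for phosphoenolpyruvate carboxykinase, pck, rose 8.65-fold, with a log2 fold change of 3.11 ± 0.19. The fructose bisphosphatase gene glpX, which is also on the glycerol list, rose 5.63-fold, and maeB, for a malic enzyme, rose 2.57-fold. The other fructose bisphosphatase gene, fbp, was the member that fell, with a log2 fold change of -0.44, a call lost without glycerol replicate 1 or 2 (adjusted p of 0.245 and 0.248). Their median log2 fold change was 0.38, with a camera adjusted p of 0.004, and the adjusted p = 0.833 with an estimated correlation.

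The TCA cycle list did not pass as a whole (median log2 fold change 0.37, camera adjusted p of 0.725, and 0.0489 in the log2 TPM table), and its members moved in opposite directions. Over all genes and adjusted over the list alone, 7 of 17 rose, 1 fell and 9 did not pass. The member that fell was mqo (b2210), for malate:quinone oxidoreductase, at 2305108 to 2306754 on the minus strand. It went from 373 ± 2 to 31.7 ± 3.0 CPM (SD, n = 2), a log2 fold change of -3.56 ± 0.12 and an 11.8-fold lower level in glycerol. Its adjusted p was 7.89e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The fumarase genes fumA and fumC rose 2.26-fold and 2.39-fold, while the log2 fold change of mdh, for the soluble malate dehydrogenase, was 0.15 and passed only without glucose replicate 2 (0.19, adjusted p of 0.00642). Only 3 members rose without glycerol replicate 1 or 2, while 9 rose and 3 fell without glucose replicate 1 and 13 rose without glucose replicate 2.

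Genes for glucose uptake were among those that fell. The gene for the glucose-specific permease of the phosphotransferase system, ptsG (b1101), went from 3003 ± 773 to 503 ± 28 CPM (SD, n = 2), a log2 fold change of -2.58 ± 0.20. The galactose and glucose transporter gene galP was 2.84-fold lower in glycerol, and ptsH and ptsI, for the general phosphotransferase proteins, had log2 fold changes of -0.46 and -0.64, calls lost without glycerol replicate 1 or 2. The glucokinase gene glk rose 1.90-fold. Of 13 list members, 1 rose, 4 fell and 8 did not pass, with the same counts adjusted over the list alone. The median log2 fold change of the glucose uptake list was -0.26, with a camera adjusted p of 0.031, and the adjusted p = 0.833 with an estimated correlation. The camera call was also lost without glycerol replicate 1 (adjusted p of 0.0592) and with a minimum of 50 counts in 2 samples (adjusted p of 0.0599). Without glycerol replicate 1, 2 members fell, and without glucose replicate 1, 8 fell.

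Among the other genes with the largest decreases were tsgA, yjcB and azuC, which were 6.26-fold, 6.27-fold and 7.38-fold lower in glycerol. The levels of yjcB and azuC were low, at 10.3 ± 3.1 and 11.5 ± 4.3 CPM in glucose (SD, n = 2). Among the largest increases was prpB (b0331), for the last enzyme of propionate breakdown by the methylcitrate cycle, from 0.82 ± 0.48 to 169 ± 22 CPM (SD, n = 2), with only 8 and 11 counts in the glucose libraries.

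Glycolysis and the pentose phosphate and Entner-Doudoroff pathways did not pass as lists. Of 13 glycolysis genes, 2 (fbaB and pykA) rose, 1 (gpmM) fell and 10 did not pass, and adjusted over the list alone 1 rose and 1 fell (median log2 fold change -0.19, camera adjusted p of 0.468). No glycolysis gene passed without glycerol replicate 1 or without glycerol replicate 2, and 2 rose and 7 fell without either glucose replicate. With upper-quartile factors, with total counts and in the log2 TPM table, 1 rose and 3 fell, and there and with factors from all but the 20 most abundant genes fbaB lost its call (0.0646 to 0.109). Of 12 pentose phosphate and Entner-Doudoroff genes, 1 rose, 3 fell and 8 did not pass, with the same counts adjusted over the list alone (median -0.08, camera adjusted p of 0.395, and 0.025 by fry). The ribose phosphate isomerase gene rpiB rose 2.78-fold and the aldolase gene eda had a log2 fold change of -0.85 ± 0.11.

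Genes for the uptake and use of carbon sources that were not in the medium rose widely. Of 65 members, 54 rose, 2 (malP and malQ) fell and 9 did not pass, and adjusted over the list alone 56 rose and 2 fell. Without glycerol replicate 1 or without glycerol replicate 2, 44 rose and 0 fell. The tryptophanase gene tnaA went from 10.4 ± 3.8 to 567 ± 7 CPM (SD, n = 2), a log2 fold change of 5.81 ± 0.24. Its neighbour tnaB, for a tryptophan transporter, had a log2 fold change of 5.60 ± 0.19 and xylF, for the xylose-binding protein, 4.32 ± 0.21. Over the 65 genes the median log2 fold change was 1.32, with a camera adjusted p of 5.07e-20, and the adjusted p = 0.667 with an estimated correlation. Many of these genes are known to need the cAMP receptor protein, and the cAMP-CRP list of 4 genes had 1 that fell and 3 that did not pass, with the same counts adjusted over the list alone (median -0.01, camera adjusted p of 0.645). These are transcript levels, and neither cAMP nor the activity of the receptor protein was measured. The adenylate cyclase gene cyaA fell, with a log2 fold change of -0.63 ± 0.12, a call lost without glycerol replicate 1 or 2 (adjusted p of 0.134 and 0.128). The fold change of crp was 0.29 ± 0.12 on the log2 scale with an adjusted p of 0.0871 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It passed with upper-quartile factors, with total counts, with factors from all but the 20 most abundant genes and in the log2 TPM table, where its adjusted p lay between 0.0286 and 0.0407, and without glucose replicate 1 or 2 (1.14e-04 and 2.93e-06).

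All 52 tested genes for flagella and chemotaxis rose, over all genes and adjusted over the list alone, and 48 of them by more than 2-fold. The flagellin gene fliC (b1923) went from 71.3 ± 7.3 to 1324 ± 3 CPM (SD, n = 2), a log2 fold change of 4.21 ± 0.15. The chemoreceptor genes tar and tap rose 19.4-fold and 12.7-fold. The genes of the master regulator, flhD and flhC, which were chosen for mention after their values were seen, rose less, with log2 fold changes of 0.99 ± 0.12 and 0.85 ± 0.19. The list's median log2 fold change was 2.12, with a camera adjusted p of 1.39e-42, and the adjusted p = 0.667 with an estimated correlation. The list took 0.0571 ± 0.0039% of counts in glucose and 0.373 ± 0.007% in glycerol (SD, n = 2).

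**Figure D3:**
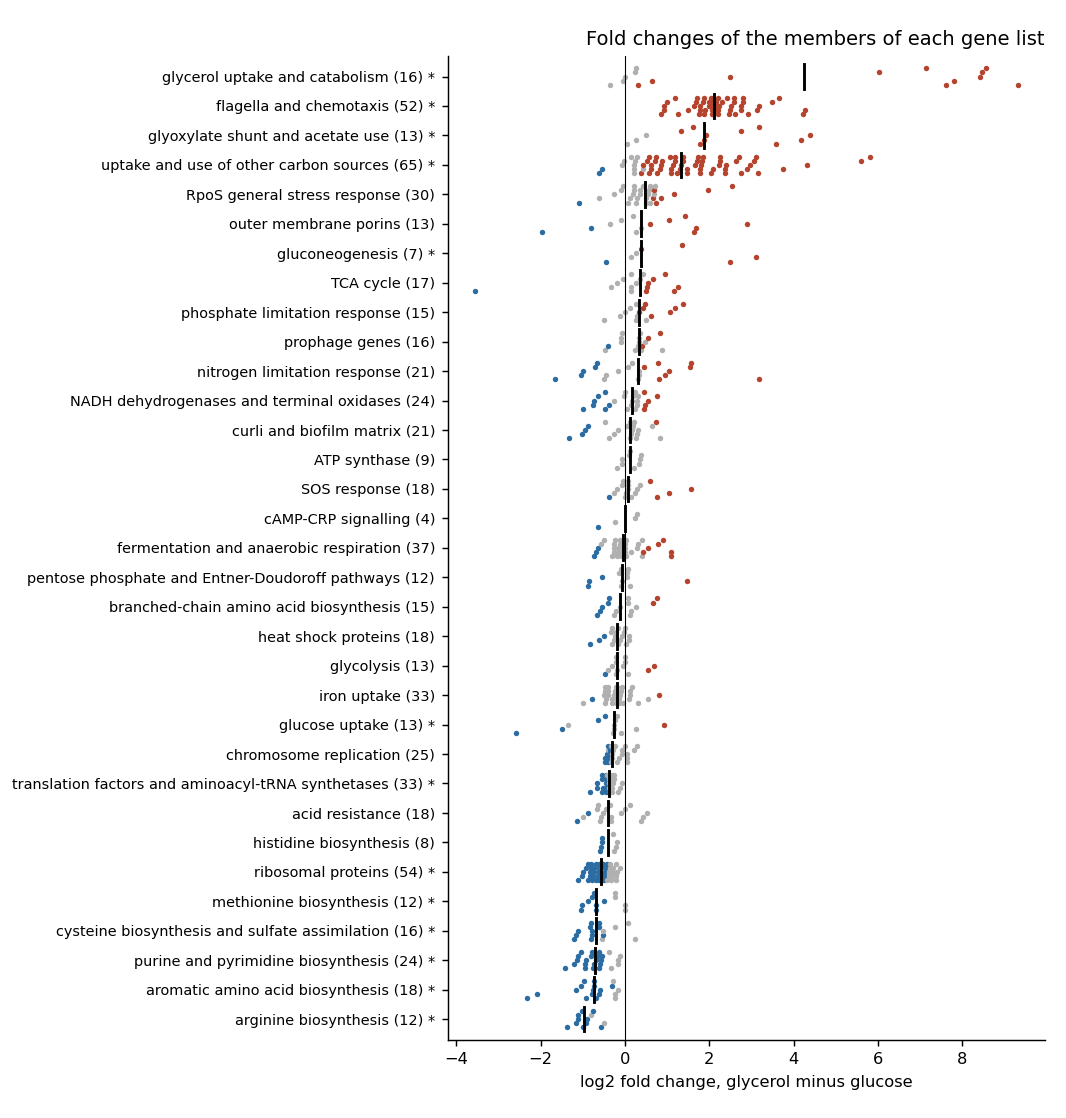
Log2 fold change, glycerol minus glucose, of each tested member of the gene lists, with red dots for members that rose, blue for members that fell, grey for members that did not pass, black bars for the median and the number of tested members in parentheses. An asterisk marks an adjusted p under 0.05 by camera with the preset correlation, a call that no list kept with an estimated correlation.

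Most ribosomal protein genes fell. Of 54 ribosomal protein genes, 0 rose, 38 fell and 16 did not pass, and adjusted over the list alone 43 fell. The gene rplI, for ribosomal protein L9, went from 1616 ± 349 to 747 ± 38 CPM (SD, n = 2), a log2 fold change of -1.11 ± 0.17. The list took 13.2 ± 1.2% of all counts in glucose and 8.95 ± 0.27% in glycerol (SD, n = 2). Its median log2 fold change was -0.56, with a camera adjusted p of 1.72e-07, and the adjusted p = 0.833 with an estimated correlation. Of 33 genes for translation factors and aminoacyl-tRNA synthetases, 0 rose, 15 fell and 18 did not pass, and adjusted over the list alone 22 fell. Of these genes 24 fell with upper-quartile factors, 27 with total counts and 23 in the log2 TPM table. That list's median was -0.39, with a camera adjusted p of 4.56e-04, and the adjusted p = 0.833 with an estimated correlation. The glucose libraries differed in both lists, with medians of -0.34 and -0.22 for replicate 1 minus replicate 2, against -0.04 and -0.01 in glycerol. Without glycerol replicate 1 or 2, 1 and 3 ribosomal protein genes and 0 and 0 translation factor genes fell, against 54 and 49, and 32 and 29, without glucose replicate 1 or 2.

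Most genes of several biosynthetic pathways fell in glycerol. In aromatic amino acid synthesis 14 of 18 genes fell, 0 rose and 4 did not pass, with the same counts adjusted over the list alone. The tyrosine pathway gene tyrA went from 618 ± 233 to 122 ± 6 CPM (SD, n = 2), a log2 fold change of -2.33 ± 0.27, and its neighbour aroF was 4.21-fold lower in glycerol. Over the 18 genes the median log2 fold change was -0.73, with a camera adjusted p of 6.34e-06. In purine and pyrimidine synthesis 19 of 24 genes fell, 0 rose and 5 did not pass, and adjusted over the list alone 20 fell. The GMP synthesis genes guaB and guaA were 2.67-fold and 2.21-fold lower in glycerol, the orotate phosphoribosyltransferase gene pyrE was 2.30-fold lower, and the list's median was -0.72 with a camera adjusted p of 5.05e-06. Both lists had an adjusted p = 0.833 with an estimated correlation.

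In arginine synthesis 10 of 12 genes fell, 0 rose and 2 did not pass, and adjusted over the list alone 12 fell. The argininosuccinate lyase gene argH had a log2 fold change of -1.38 ± 0.20 and argG, for the step before it, -1.17 ± 0.20. The arginine list's median was -0.97, with a camera adjusted p of 8.61e-04. In methionine synthesis 8 of 12 genes fell, 0 rose and 4 did not pass, with the same counts adjusted over the list alone. The genes metL and metK were 2.05-fold and 2.04-fold lower in glycerol, and the list's median was -0.68 with a camera adjusted p of 0.00348. In cysteine synthesis and sulfate assimilation 11 of 16 genes fell, 0 rose and 5 did not pass, and adjusted over the list alone 14 fell. The sulfate activation genes cysC and cysD had log2 fold changes of -1.20 ± 0.18 and -1.16 ± 0.21, and the list's median was -0.69 with a camera adjusted p of 0.00547. All 3 of these lists had an adjusted p = 0.833 with an estimated correlation.

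The glucose libraries differed in these pathways too. All 12 arginine, 16 cysteine, 24 purine and pyrimidine and 18 aromatic genes and 11 of 12 methionine genes were lower in glucose replicate 1 than in glucose replicate 2, with medians of -0.61, -0.61, -0.38, -0.22 and -0.22 on the log2 scale. The medians of glycerol replicate 1 minus replicate 2 lay between -0.01 and 0.05. The genes that fell without glycerol replicate 1 numbered 5 for arginine, 2 for methionine, 2 for cysteine, 7 for aromatic amino acids and 8 for purines and pyrimidines. Without glycerol replicate 2 they numbered 6, 2, 3, 7 and 10, without glucose replicate 1 they numbered 12, 10, 14, 18 and 24, and without glucose replicate 2 they numbered 12, 10, 14, 18 and 20.

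Histidine and branched-chain amino acid synthesis did not pass as lists. Of 8 histidine genes 4 fell, 0 rose and 4 did not pass, with the same counts adjusted over the list alone (median -0.41, camera adjusted p of 0.108). All 8 were lower in glucose replicate 1 than in glucose replicate 2. Without glycerol replicate 1 or 2 no histidine gene passed, and without glucose replicate 1 all 8 fell and the list passed (adjusted p of 0.00393), as it did with limma-voom (0.0197) and in the log2 TPM table (0.0117). Of 15 branched-chain genes 2 rose, 5 fell and 8 did not pass, with the same counts adjusted over the list alone (median -0.12, camera adjusted p of 0.426). The 2 that rose were ilvB and ilvN, for the 2 subunits of an acetolactate synthase, at 1.59-fold and 1.70-fold. The call of ilvB was lost without glycerol replicate 1 or 2, where 1 gene of the list rose and 0 fell.

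**Figure D4:**
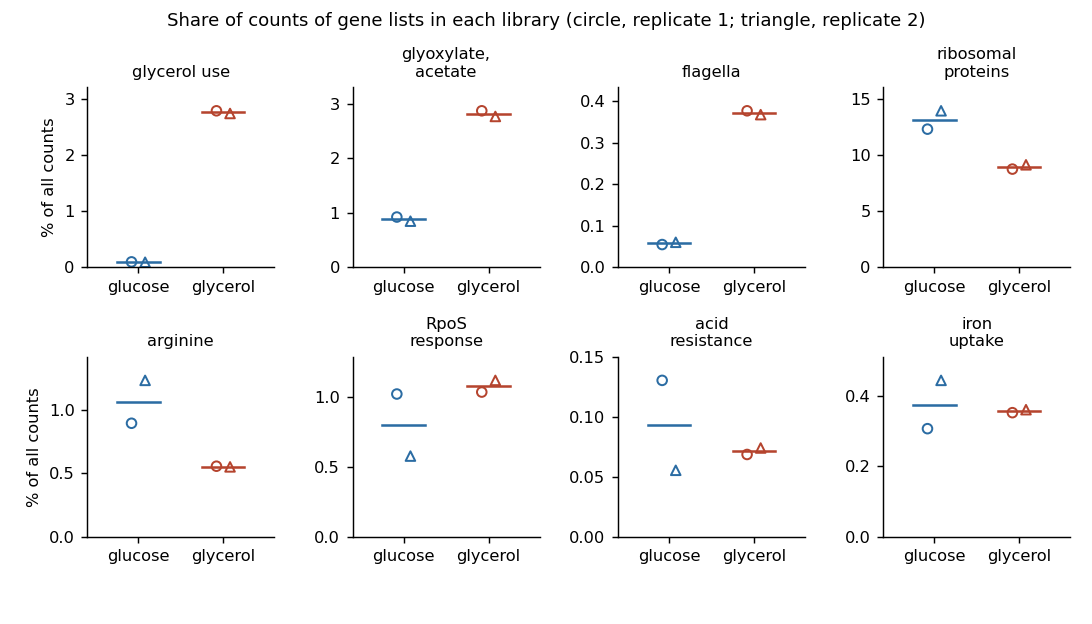
Share of all counts, in percent, of 8 gene lists in each library, with circles for replicate 1, triangles for replicate 2 and bars for the mean of each group (n = 2). The glycerol list rises from under 0.1% to over 2.7%, and the shares of the RpoS, acid resistance and iron lists lie farther apart between the glucose replicates than between the glycerol replicates.

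Of 30 genes on the RpoS general stress list, 7 rose, 1 (osmY) fell and 22 did not pass, and adjusted over the list alone 5 rose and 1 fell. The call of osmY was lost without glycerol replicate 1 (0.0685) and in the log2 TPM table (0.0646). The glutarate hydroxylase gene glaH rose 5.78-fold, from 45.7 ± 1.8 to 265 ± 3 CPM (SD, n = 2), ychH rose 3.92-fold and ecnB, for a small lipoprotein, 2.23-fold. The gene rpoS (b2741), for the stationary phase sigma factor, had a log2 fold change of 0.67 ± 0.17 and an adjusted p of 0.0159 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, a call lost without glycerol replicate 1 or 2 (0.157 and 0.18). The list's median was 0.47, with a camera adjusted p of 0.108. The list took 1.02% of counts in glucose replicate 1 and 0.578% in glucose replicate 2, against 1.04% and 1.12% in the glycerol replicates, and its median of glucose replicate 1 minus replicate 2 was 0.69. With the replicate number as a block the list passed (median 0.49, adjusted p of 0.0211), as it did with limma-voom (0.00873) and without glucose replicate 1 (median 0.84, adjusted p of 4.61e-08). The members that rose numbered 19 with the block and 12 by DESeq2, with 2 that fell in each, and 4 with upper-quartile factors, with total counts and in the log2 TPM table. Without glucose replicate 1, 28 members rose and 1 fell, without glucose replicate 2, 14 rose and 8 fell, and without glycerol replicate 1 or 2, 4 and 3 rose.

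Of 18 acid resistance genes 0 rose, 2 fell and 16 did not pass, with the same counts adjusted over the list alone (median -0.41, camera adjusted p of 0.262). The 2 that fell were mdtE and mdtF, for parts of a multidrug efflux pump, at 2.19-fold and 1.84-fold lower levels in glycerol, and mdtF lost its call with total counts (0.0559), in the log2 TPM table (0.107) and without glycerol replicate 2 (0.0505). The acid resistance list took 0.131% of counts in glucose replicate 1 and 0.0555% in glucose replicate 2, against 0.0687% and 0.0741% in glycerol. Without glucose replicate 2, 14 members fell and the list passed (median -0.78, adjusted p of 1.82e-04), and without glucose replicate 1, 7 rose and 3 fell. The glutamate decarboxylase genes gadA and gadB are nearly identical copies, so that the level of each is uncertain, and gadA stood at -1.17 without glucose replicate 2 and at 0.28 without glucose replicate 1.

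Of 33 iron uptake genes 1 rose, 1 fell and 31 did not pass, and adjusted over the list alone 1 rose and 0 fell (median -0.20, camera adjusted p of 0.278). The gene feoA, of the ferrous iron transporter, rose 1.75-fold, and fhuB, which fell, lost its call without glycerol replicate 1 or 2 (0.119 and 0.0696). The iron list took 0.308% of counts in glucose replicate 1 and 0.446% in glucose replicate 2, against 0.353% and 0.362% in glycerol. Without glucose replicate 1, 26 members fell and the list passed (median -0.59, adjusted p of 5.79e-04), and without glucose replicate 2, 14 rose and 3 fell. Of 18 heat shock genes 0 rose, 3 fell and 15 did not pass, and adjusted over the list alone 1 fell (median -0.19, camera adjusted p of 0.145). The 3 were ibpB, lon and ftsH, and each lost its call without glycerol replicate 1 or 2. The call of ibpB was also lost without glucose replicate 1 (0.191), with 3 of the other scalings, by DESeq2 and in the log2 TPM table (0.0543 to 0.144). The heat shock list passed without glucose replicate 2 (median -0.36, adjusted p of 0.00687), and 16 of its 18 genes were higher in glucose replicate 1 than in glucose replicate 2.

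The genes for respiration moved in both directions. Of 24 genes for NADH dehydrogenases and terminal oxidases, 5 rose, 7 fell and 12 did not pass, with the same counts adjusted over the list alone. The gene ndh, for the NADH dehydrogenase that pumps no protons, had a log2 fold change of -0.99 ± 0.11, and nuoA, for a subunit of the proton-pumping enzyme, 0.76 ± 0.12. The list's median was 0.16, its mean -0.005 and its camera direction down (adjusted p of 0.645), so that these differ in sign. Of 9 ATP synthase genes 0 passed edgeR's quasi-likelihood test, over all genes or adjusted over the list alone, 3 had an unadjusted p under 0.05, and 0 passed by DESeq2 or limma-voom (median 0.11, camera adjusted p of 0.883). With upper-quartile factors, with total counts, with factors from all but the 20 most abundant genes and in the log2 TPM table, 3 rose, and 2 rose with a minimum of 50 counts in 2 samples. The log2 fold changes of atpA and atpD were 0.11 ± 0.18 and -0.07 ± 0.18, and neither passed. Without glucose replicate 2, 7 genes rose and 0 fell, with atpA and atpD at 0.34 and 0.16, and without glucose replicate 1, 3 rose and 4 fell, with atpD at -0.27. Of 37 genes for fermentation and anaerobic respiration 6 rose, 3 fell and 28 did not pass, and adjusted over the list alone 5 rose and 1 fell (camera adjusted p of 0.738). Its median of -0.05 and its camera direction, down, differ in sign from its mean of 0.03. The fumarate reductase genes frdA, frdB and frdC rose 2.13-fold, 2.13-fold and 1.88-fold.

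Of 13 outer membrane porin genes and their regulators, 6 rose, 2 fell and 5 did not pass, and adjusted over the list alone 7 rose and 3 fell (median 0.39, camera adjusted p of 0.262). The maltoporin gene lamB, which is also on the list of other carbon sources, rose 7.47-fold, from 143 ± 66 to 1061 ± 1 CPM (SD, n = 2), and ompW rose 3.22-fold. The gene ompX was 3.90-fold lower in glycerol, with a log2 fold change of -1.96 ± 0.15. The other gene that fell, ompC, chosen after its values were seen, had a log2 fold change of -0.80, a call lost with upper-quartile factors, with total counts, with factors from all but the 20 most abundant genes, with a minimum of 50 counts in 2 samples, with limma-voom and in the log2 TPM table (adjusted p of 0.0601 to 0.164), and without glycerol replicate 1 or 2 (0.196 and 0.192). The most abundant gene of the glycerol libraries, ompF, rose 2.08-fold, a call lost without glycerol replicate 1 or 2 (0.0828 and 0.056). Without glucose replicate 2, 4 members fell, and 1 fell without either glycerol replicate. The porin list passed without glucose replicate 1 or 2 (0.0217 and 0.0351) and by fry (0.0164), which tests whether a list's genes move one way without comparing them with other genes.

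Of 21 genes of the nitrogen limitation list, 8 rose, 5 fell and 8 did not pass, and adjusted over the list alone 8 rose and 6 fell (median 0.30, camera adjusted p of 0.738). The gene ddpX, for a D-alanyl-D-alanine dipeptidase, rose 9.07-fold and astC, of arginine breakdown, 2.96-fold. The largest decrease was that of glnK, for a regulatory protein, with a log2 fold change of -1.65 ± 0.54, a call lost with upper-quartile factors, with total counts, with factors from all but the 20 most abundant genes and with limma-voom (adjusted p of 0.052 to 0.0654), without glycerol replicate 1 or 2 (0.168 and 0.21) and without glucose replicate 2 (0.0688). The glutamate synthase genes gltB and gltD, chosen after their values were seen, had log2 fold changes of -0.99 ± 0.15 and -1.05 ± 0.14, and both lost the call without glycerol replicate 1 (0.0983 and 0.051), gltB also without glycerol replicate 2 (0.0772). Of this list 6 members rose and 0 fell without glycerol replicate 1, 5 rose and 1 fell without glycerol replicate 2, and 8 fell without glucose replicate 1. Of 15 genes of the phosphate limitation list, 7 rose, 0 fell and 8 did not pass, with the same counts adjusted over the list alone (median 0.34, camera adjusted p of 0.344). The ugp genes for the uptake of glycerol 3-phosphate, which are also on the list of other carbon sources, rose most, with 2.60-fold for ugpB, a call lost without glycerol replicate 1 or 2 (0.0909 and 0.101), and 2.27-fold for ugpA. The phosphate list passed with limma-voom (0.0322) and without glucose replicate 1 (0.028), and 2 and 3 members rose without glycerol replicate 1 or 2, against 11 without glucose replicate 1.

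Of 18 SOS response genes 4 rose, 1 fell and 13 did not pass, with the same counts adjusted over the list alone (median 0.08, camera adjusted p of 0.645). The toxin gene tisB rose 2.94-fold and the cell division inhibitor gene sulA 2.06-fold, while lexA and recA, for the regulators of the response, did not pass, with log2 fold changes of -0.01 and 0.23. The gene recA passed with total counts (0.0437), in the log2 TPM table (0.0447) and without glucose replicate 2. Of 21 genes for curli and biofilm matrix 1 rose, 4 fell and 16 did not pass, with the same counts adjusted over the list alone (camera adjusted p of 0.395). Its median of 0.12 differs in sign from its mean of -0.07 and its camera direction, down. The 4 that fell are fim genes for type 1 fimbriae, and fimA, for their main subunit, was 2.52-fold lower in glycerol. Of 16 prophage genes 3 rose, 1 fell and 12 did not pass, with the same counts adjusted over the list alone (median 0.33, camera adjusted p of 0.738), and dicA rose 1.77-fold. Of 25 chromosome replication genes 0 rose, 8 fell and 17 did not pass, with the same counts adjusted over the list alone (median -0.31, camera adjusted p of 0.0628). The replication list passed with limma-voom (0.00871), in the log2 TPM table (0.00651) and without glucose replicate 1 (0.027), and no member fell without glycerol replicate 1 or 2. Of 16 plasmid marker and reporter gene names, 0 were in the files, which list chromosomal coding sequences.

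Counts of several smaller groups also moved by over 1.5 times without a library. Of the pentose phosphate and Entner-Doudoroff genes, 1 rose and 1 fell without either glycerol replicate, 4 rose and 5 fell without glucose replicate 1, and 1 rose and 6 fell without glucose replicate 2. The NADH dehydrogenase and oxidase genes that rose or fell numbered 1 and 3 without glycerol replicate 1, 1 and 2 without glycerol replicate 2, 10 and 9 without glucose replicate 1, and 13 and 7 without glucose replicate 2. Of the fermentation and anaerobic respiration genes, 4 rose and 0 fell without either glycerol replicate, and 6 fell without glucose replicate 2. Of the curli and biofilm matrix genes, 8 rose without glucose replicate 1, and 3 rose and 7 fell without glucose replicate 2. Of the prophage genes, 1 rose without either glycerol replicate and 5 rose without glucose replicate 1. Of the branched-chain genes, 4 rose and 8 fell without glucose replicate 1. No heat shock gene passed without either glycerol replicate, 4 rose and 6 fell without glucose replicate 1, and 0 rose and 16 fell without glucose replicate 2. Of the replication genes, 2 rose and 16 fell without glucose replicate 1, and 1 rose and 13 fell without glucose replicate 2. Without glucose replicate 2, 2 genes each of the cAMP-CRP list and of cysteine synthesis rose. With all libraries, 13 replication genes fell with upper-quartile factors, 4 acid resistance and 6 iron uptake genes fell with the replicate block, and 5 prophage genes and 2 cAMP-CRP genes rose in the log2 TPM table. The iron uptake genes that rose numbered 3 with total counts and with factors from all but the 20 most abundant genes, and 3 curli and biofilm matrix genes rose with the replicate block. The NADH dehydrogenase and oxidase genes that rose numbered 8 with total counts, with factors from all but the 20 most abundant genes and in the log2 TPM table. Of the fermentation and anaerobic respiration genes, 0 fell by DESeq2 and 1 fell with limma-voom and in the log2 TPM table. With limma-voom and a weight per group, an alternative chosen after the data were seen, 24 translation factor genes and 5 heat shock genes fell and 13 RpoS list members, 3 ATP synthase genes and 3 iron uptake genes rose.

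Along the chromosome, the log2 fold changes were weakly correlated with distance from the replication origin. Over 4029 genes Spearman's rho was 0.091, with a 95% interval of 0.028 to 0.156 from a bootstrap over blocks of 40 neighbouring genes. The two-sided p was 0.0181 over all circular shifts of the gene order. The formal limit of that p is 0.00025, but simulated counts with a slope of 0.2 log2 units per Mb gave only 0.0168. The slope of the real data was 0.0714 log2 units per Mb, with a 95% interval of -0.0194 to 0.162 that holds 0. This is a correlation across genes, which are not independent replicates. Simulated counts with nothing changed gave a p of 0.0303 by the same circular shifts, in a single draw. Over 200 draws with no gradient, 5% gave a p under 0.05, or 6% with correlated neighbours. That draw therefore does not show a fault of the test. The intervals of rho and of the slope differ in whether they hold 0, so the evidence of a gradient is weak. The median log2 fold change was 0.19 in the 579 genes at 2 to 2.4 Mb from the origin and lay between -0.03 and 0.03 in the 5 bins nearer to it. Without glycerol replicate 1, rho was 0.087 with a p of 0.0814.

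The deposited log2 TPM table holds the same 4 libraries, so it is no independent measurement. Over the 4029 tested genes, the difference of group means in that table and the log2 fold change from the counts had a Pearson correlation of 0.988 and a Spearman correlation of 0.9952 across genes.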

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

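The count of genes higher by more than 2-fold stayed within 1.5 times its value, at 398 to 523, and every named gene that was called kept its direction under every alternative that was run. The alternatives chosen after the data were seen were limma-voom with a weight per group and the fit without the RpoS and acid resistance lists. Without 1 library the lone sample of its group was assumed to vary like the other group, and genes called ranged from 763 without glycerol replicate 1 to 2432 without glucose replicate 1, against 1555. Genes lower in glycerol ranged from 193 to 1224, genes lower by more than 2-fold from 88 to 154, lists higher from 5 to 8, lists lower from 7 to 11, and rho along the chromosome from 0.062 to 0.11, with 0.087 and a p of 0.0814 without glycerol replicate 1. The spread of the glucose pair, wider than that of the glycerol pair, is the only spread left when a glycerol library is left out. It may account for the lower counts there. Fewer libraries alone are argued against as the cause, since the fits without a glucose library rest on as many libraries. Those fits called more genes than the fit with all libraries. The cause was not tested further. Of the genes called without glycerol replicate 1 or 2, 752 and 765 were among the 1555. The ATP synthase gene atpD went from -0.07 to -0.27 without glucose replicate 1 and 0.16 without glucose replicate 2, and gadA from -0.64 to 0.28 and -1.17, in both cases past the test on either side, and the cause was not tested.

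With all libraries, the other alternatives gave 1329 to 1704 genes, the highest with the replicate block (1681 with the replicate numbers crossed), apart from 903 at an adjusted p of 0.01, where 331 were lower. Genes higher numbered 572 to 942 and genes lower by more than 2-fold 74 to 107. With an estimated correlation 0 lists were higher and 0 lower, against 5 and 8. By fry 6 lists were higher, among them those 5, and 1 was lower, the pentose phosphate list, while none of those 8 passed. The cause of these differences was not tested. Of 164 named genes, 146 were called, 138 of them in every alternative with all libraries and 105 also without each library. Without a library, calls of named genes were both lost and gained, and 2 evaluations, of atpD and gadA, reversed in sign. The other alternatives lost 27 calls and gained 16. Shares of counts moved by more than the spread of replicates in 117 of 132 evaluations with another denominator. Scaling moved the median log2 fold change of all genes to between -0.001 and 0.045. Depth limits what can be said of the 326 genes with too few counts to be tested.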

Other observations

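The groups in this and the next paragraph were chosen after their values were seen, so their tests are not independent evidence, and none kept its camera call with an estimated correlation (adjusted p = 0.118 to 0.309 with an estimated correlation). Further genes for the breakdown of other compounds rose in glycerol. All 5 genes for propionate use rose, with log2 fold changes of 7.10 ± 0.16 for prpC and 7.28 ± 0.18 for prpD. Of 11 fatty acid beta-oxidation genes, 9 rose and 2 did not pass, and fadB went from 55.7 ± 5.3 to 456 ± 15 CPM (SD, n = 2). All 7 genes of the gat cluster, for galactitol uptake and use, rose, and gatZ went from 4003 ± 706 to 16850 ± 610 CPM (SD, n = 2). All 6 genes for acetoacetate and short-chain fatty acid use, 3 for pseudouridine use, 5 for 4-aminobutyrate and glutarate use and 5 of the ydcSTUV transport cluster rose, with psuK at 4.12 ± 0.21, lhgD at 2.19 ± 0.14 and ydcS at 2.80 ± 0.15 on the log2 scale.

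All 6 biotin synthesis genes fell, with log2 fold changes of -2.07 ± 0.21 for bioC and -2.01 ± 0.15 for bioF. Of 12 serine and lysine synthesis genes, 11 fell and 1 did not pass, and serA, for the entry step of serine synthesis, was 2.31-fold lower in glycerol. Of 4 ribosome hibernation genes, 3 rose, of which raiA and rmf, whose products bind idle ribosomes, stood at 2.20 ± 0.27 and 1.95 ± 0.17. The third, hpf, stood at 0.35 and lost its call with total counts, by DESeq2 and in the log2 TPM table (adjusted p of 0.0658 to 0.0906) and without glycerol replicate 1 or 2 (0.305 and 0.237). All 4 genes of the manganese-dependent ribonucleotide reductase rose, with nrdE at 1.16 ± 0.10. In all, 45 runs of at least 3 neighbouring genes on the same strand, 41 higher and 4 lower, held 190 genes that changed by more than 2-fold the same way.

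The tests of depth, culture state, gene clusters, dosage, scaling and abundance as the whole cause below were chosen after the result was seen, and the other tests of length and abundance trends and of background before. Depth is argued against as the source of the wider spread of the glucose pair, because after thinning to equal depth the SD of the log2 ratio of replicates was 0.295 in glucose and 0.0974 in glycerol, a ratio of 3.03. A trend with coding length or abundance is argued against too, since the median difference of the RpoS list between the glucose libraries was 0.749 after the trend was removed and 0.689 before. A candidate explanation is a different culture state of the glucose flasks, since the RpoS list minus the ribosomal protein list differed by 1.03 between the glucose libraries and by -0.09 between the glycerol libraries. It cannot be told apart from other differences between the libraries, because no label records the state of a culture beyond the OD600.

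The correlation of fold changes with distance from the origin does not rest on a few gene clusters with large changes, since rho was 0.11 without genes changed by more than 2-fold (95% interval 0.049 to 0.169). After a trend with abundance was removed, rho was 0.073 (p of 0.0107 over circular shifts, 95% interval 0.016 to 0.13). That interval is positive throughout, but a p of such a size does not by itself tell a gradient from none. Whether abundance is the whole cause is therefore not decided. A trend with abundance as a part of the cause stays open, since that interval reaches under 0.5 of the value before. A dosage gradient along the whole replication arm cannot be told apart from a change near the terminus alone, since the slope within 1.6 Mb of the origin was -0.0485 log2 units per Mb with a 95% interval of -0.212 to 0.147, which holds the slope of 0.0714 over the whole chromosome. A difference in growth rate between the carbon sources, which could change dosage, was not tested.

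Most genes changed by more than 2-fold were higher in glycerol (81.7%). With the tested genes split into 10 groups by abundance, the median log2 fold change was 0.24 in the least abundant group and -0.26 in the most abundant. Whether this trend contributes to the share of 81.7%, or to the lists that fell, was not tested. That share was between 80.7% and 84.5% over 4 other scalings of the libraries. These scalings moved the median log2 fold change of all genes only to between -0.001 and 0.045. Such small shifts could hardly change the share, so they do not decide whether scaling is a source of it. A uniform background of reads in the glycerol libraries is argued against. The background of the highest glycerol library minus that of the lowest glucose library was 0.325 TPM. After it was taken from the glycerol values, 96% of the genes higher by more than 2-fold stayed so in TPM. The carbon source itself stays open as a biological explanation and was tested by no other comparison.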
